A study of Mus musculus with 8 samples.

How the data were processed

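ATAC-seq libraries of NIH3T3 cells cultured for 24 h on G128 or G2 were compared, with 2 libraries in each group. Groups and replicate numbers were taken from the sample titles. Each library had its own peak list in the narrowPeak format, so peaks had been called per library and not on pooled replicates. The 4 RNA libraries of the series were not analysed here.

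Per the submitters' processing notes, the tools used were Bowtie2 2.2.5, SAMtools 1.7, Genrich 0.5, HISAT2 2.1.0, featureCounts 1.5.0-p1 and deepTools, and the genome build was mm9. The notes used here give neither the role of each tool nor its settings. How reads were shifted for the transposase, and how duplicates, mitochondrial reads and repeats were treated, is not given in the sources used here. Per the labels' protocols, the cells were digested with Tn5 and the DNA was amplified by PCR.

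The lists deposited by the authors hold a position, a score, a signal, −log10 values of p and q, and the offset of the summit for each peak. The deposited signal of a peak is the value the peak caller gave it, and the smallest in each list was 20.0. The deposited score equalled 1000 times the signal divided by the peak width, capped at 1000, in 100% of peaks of each list within a tolerance of 1. The deposited −log10 q-values started at 1.46, 1.49, 1.51 and 1.54 in G128 replicate 1, G128 replicate 2, G2 replicate 1 and G2 replicate 2. These values are the authors' and belong to their own list, so they were used to rank and filter peaks within a list. All coordinates are those of the files, on mm9, and are given from 1.

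The depth of a library and the height of each summit were recovered from the deposited −log10 p-values. Each list held only 501 to 806 distinct p-values, and the normal quantiles of the lowest 100 of them were linear in the logarithm of successive whole numbers. The starting number was the one with the best fit, whose root mean square error was 1.45e-07 to 1.58e-07, against 0.00164 to 0.00244 for the next best. This is the pattern of a whole number of overlapping intervals at the summit tested against a log-normal background. The fit gave the background mean, which differed between libraries, and a spread of 0.944 that was the same in all 4 libraries to 3 digits. All recovered summit pileups lay within 0.000853, 0.00139, 0.00147 and 0.00179 of a whole number in the 4 libraries in the order above. The median summit pileup was 46, 60, 47 and 59 intervals, and the highest 3618, 4139, 3350 and 3779. A summit divided by the background mean is called the summit over the background. The recovery was chosen after the values had been seen. When tested on simulated data with the same numbers of peaks, it returned the pileup of 100% of peaks in each library. These data were simulated from the same log-normal form, so the result checks the computation and not that form.

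Peaks of the 4 lists were merged into regions where they shared at least 1 bp, and a library had a region if it had a peak in it. Regions in both libraries of one group and in neither of the other were called G128-only or G2-only, and regions in all 4 libraries shared. A region's summit in a library was the highest of the summits of that library's peaks in it. Shares are given with Wilson intervals at the 95% level. Libraries were compared pairwise by the share of peaks overlapping by at least 1 bp and by the Jaccard index from bedtools 2.31.1. Values per library were compared between groups by two-sided exact permutation tests over the 6 assignments. The distribution over chromosomes was compared by a chi-square statistic with 100000 permutations. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

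The regions named were, in each direction, the 10 regions of a single group with the best worst rank by signal over the 2 lists that had them. This rule, the groups, the tests and most alternatives were fixed before the data were examined. The alternatives concerned the overlap that counts as shared, the caller's threshold, the number of peaks per list, peak width, chromosomes, the replicate block and leaving out each library in turn.

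A test of summit height in single shared regions, chosen after the data were seen, used limma 3.58.1 in R 4.3.3. The values were log2 summits over the background, from which each library's median over the shared regions was subtracted. Adjusted p-values are Benjamini-Hochberg values over 27768 regions, called at 0.05. When tested on simulated data for this comparison, with 27768 regions of which 100 were changed by 0.5 and 100 by 1 on the log2 scale, 12 and 72 of these were recovered, beside 8 false calls. The simulation assumed a dispersion of 0.01 in every region and no general shift of summits between libraries. Where the real libraries vary otherwise, these numbers need not hold.

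Genomic position relative to genes, the gene lists and the sequence motifs fixed earlier were not tested, because no genome sequence or annotation of mm9 was used here and coordinates were not converted between builds. Regions are therefore named by position alone. Because only peaks above the caller's threshold are listed, a region below the threshold in a library has no value there.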

Results

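Chromatin accessibility was measured by ATAC-seq in NIH3T3 cells, an immortalised fibroblast line from mouse embryos, after 24 h of culture on G128 or on G2. In ATAC-seq the Tn5 transposase places sequencing adapters into DNA that nucleosomes leave exposed, so that reads pile up over accessible regions. The labels do not say what the names G128 and G2 stand for, and the series is about how hydrogels of polyvinyl alcohol and gelatin affect adhesion and chromatin. The comparison of the 2 cultures addresses how accessibility differs when the same cells adhere under different conditions. Each group held 2 libraries, and each library had its own peak list on the mouse genome build mm9. The 4 RNA libraries of the series were not analysed here.

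The depth of each library was read from the steps of its p-values, as the mean of the background to which the peak caller compared each position. This background mean was 1.05 overlapping intervals per bp in G128 replicate 1 and 1.41 in G128 replicate 2. It was 1.10 in G2 replicate 1 and 1.37 in G2 replicate 2. The group means were 1.23 ± 0.253 in G128 and 1.23 ± 0.190 in G2 (SD, n = 2 each), with replicate 1 the shallower library in both. The ratio of G2 to G128 was 1.04 between the replicates 1 and 0.970 between the replicates 2. The weakest peak of each list had a summit of 20, 26, 20 and 25 intervals in the order above, which was 19.0, 18.4, 18.2 and 18.3 times the background mean. Nothing in the labels says that the replicates came from separate cultures, so p-values between the groups measure only the spread between these samples, which may be technical.

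The G2 libraries had more peaks than the G128 libraries and covered more of the genome. G2 replicate 1 had 42358 peaks and G2 replicate 2 had 41585, against 32540 in G128 replicate 1 and 37695 in G128 replicate 2. The means were 41971.5 ± 547 peaks on G2 and 35117.5 ± 3645 on G128 (SD, n = 2 each), a ratio of 1.20. Peaks covered 21.3 ± 1.32 Mb on G2 and 17.2 ± 2.42 Mb on G128 (SD, n = 2 each), a ratio of 1.24. Peak width did not follow the groups, with a median of 367 and 368 bp in the G128 libraries and of 351 and 393 bp in the G2 libraries.

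For peaks and for bases covered, both G2 libraries lay above both G128 libraries, and the two-sided exact permutation test gave p = 0.333. This is the smallest p that the 6 assignments of 2 against 2 libraries allow, so this test could not pass a threshold of 0.05 for any value. The group means differed by 6854 peaks, and the spread between the G128 libraries, seen in the plot of peaks against background mean, was 3645 peaks (SD).

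**Figure D1:**
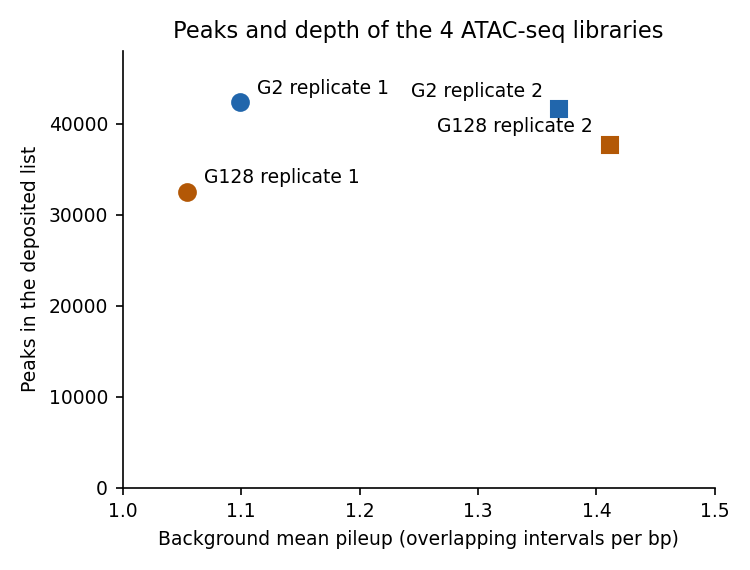
Number of peaks in each of the 4 lists against the library's background mean pileup (overlapping intervals per bp), with G128 in orange, G2 in blue, replicate 1 as circles and replicate 2 as squares. At each replicate number the G2 list was longer, 42358 against 32540 and 41585 against 37695 peaks, at background means of 1.10 against 1.05 and 1.37 against 1.41.

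Nearly all peaks of the G128 libraries overlapped peaks on G2, while the reverse held less often. Of the 32540 peaks of G128 replicate 1, 97.0% overlapped a peak of G2 replicate 1 (Wilson 95% interval 96.8 to 97.2%) and 97.6% a peak of G2 replicate 2 (97.4 to 97.7%). Of the 37695 peaks of G128 replicate 2, 93.2% (92.9 to 93.5%) and 94.6% (94.3 to 94.8%) did so. Of the peaks of G2 replicate 1, 70.6% (70.2 to 71.1%) overlapped a peak of G128 replicate 1 and 81.8% (81.4 to 82.1%) a peak of G128 replicate 2. For G2 replicate 2 these shares were 70.3% (69.9 to 70.8%) and 81.4% (81.1 to 81.8%). Within G128, 95.9% of the peaks of replicate 1 overlapped replicate 2 and 79.3% of those of replicate 2 overlapped replicate 1, both below their shares with the G2 libraries, whose lists were longer. Within G2 the shares were 91.1% and 89.7%. All intervals given here cover counting error only.

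Measured as the Jaccard index of covered bases, which is the shared length over the joint length, the G2 libraries overlapped each other by 0.806 and the G128 libraries by 0.753. G128 replicate 2 overlapped both G2 libraries more, by 0.780 for G2 replicate 1 and 0.774 for G2 replicate 2, than it overlapped G128 replicate 1. G128 replicate 1 overlapped G2 replicate 1 by 0.709 and G2 replicate 2 by 0.671. The mean over the 2 pairs within groups was 0.780 ± 0.0370 and over the 4 pairs between groups 0.733 ± 0.0526 (SD). The difference of 0.0464 was smaller than the spread among the pairs between groups, and the pairs share libraries, so no test was made.

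Far more regions had peaks only on G2 than only on G128. Merging the 4 lists gave 45915 regions, of which 27768 (60.5%, Wilson 95% interval 60.0 to 60.9%) had a peak in all 4 libraries. A further 3820 regions (8.32%, 8.07 to 8.58%) had a peak in both G2 libraries and in neither G128 library. Only 170 regions (0.370%, 0.319 to 0.430%) had a peak in both G128 libraries and in neither G2 library, a ratio of 22.5 between the groups. The G2-only regions covered 0.950 Mb, the G128-only regions 0.0361 Mb and the shared regions 20.3 Mb.

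The patterns with 2 libraries that followed no group held 795 regions for both replicates 2, and 119 regions for both replicates 1. The crossed patterns held 569 regions for G128 replicate 2 with G2 replicate 1, and 151 for G128 replicate 1 with G2 replicate 2. The 170 G128-only regions were therefore within the range of these patterns, and the 3820 G2-only regions were above all of them. Each of these patterns joined a G2 list to a shorter G128 list, while the G2-only pattern joined the longest lists (42358 and 41585 peaks). The comparison therefore cannot separate a difference between the groups from the length of the lists. The largest class after the shared regions, 4355 regions, was found in every library but G128 replicate 1. No test per region was made, since an exact test of presence in 2 against 2 libraries cannot give a p below 0.333.

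The size of this difference depended on the peaks compared. With the same number of peaks from each list, the 32540 strongest by signal, 1385 regions were G2-only and 542 G128-only, and with the strongest 10000 the counts were 262 and 266. No G2-only or G128-only region of the full lists was among the strongest 10000 of both its lists (best worst ranks 12824 and 20733). The 262 and 266 regions therefore had a listed peak of the other group in the full lists, and these counts do not test the excess. With 50% reciprocal overlap in place of 1 bp, 4379 regions were G2-only and 1137 G128-only. Without G128 replicate 1, and so with the G128 group resting on 1 library, the counts were 4433 and 1224, and without G128 replicate 2 they were 8221 and 469. Without G2 replicate 1 they were 6921 and 363, and without G2 replicate 2 they were 6922 and 453.

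**Figure D2:**
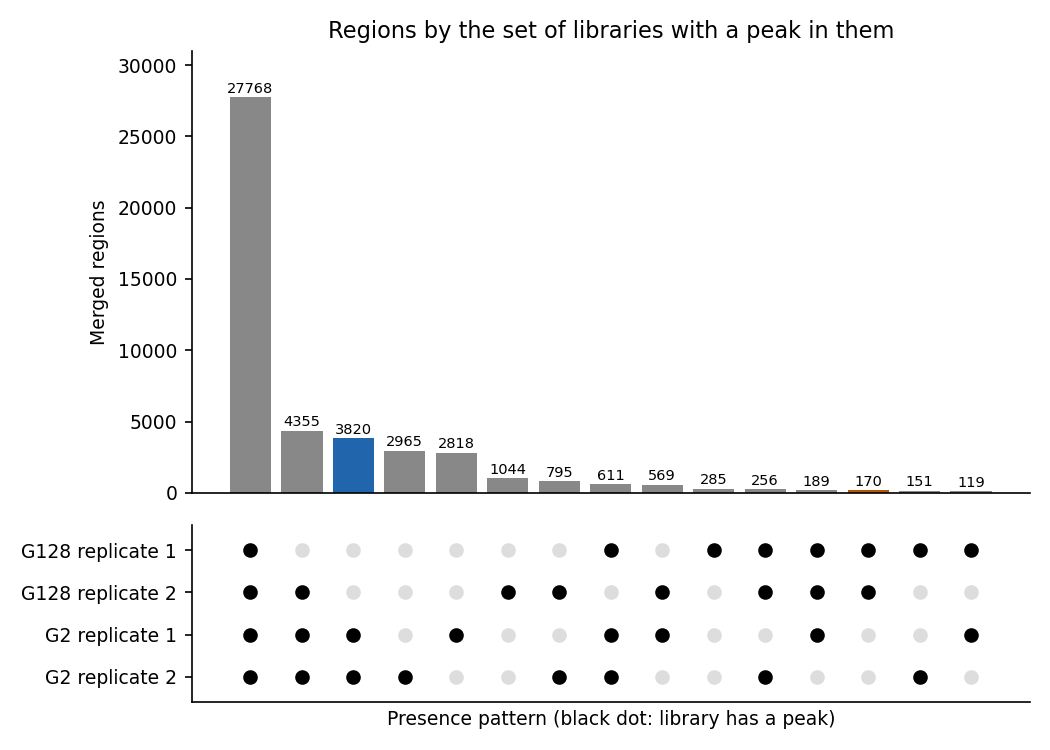
Number of merged regions (vertical axis) for each set of libraries with a peak in them, marked by the black dots, with the G2-only set in blue and the G128-only set in orange. The set of all 4 libraries held 27768 regions, the G2-only set 3820 and the G128-only set 170.

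Regions of a single group were narrow and had weak peaks. The G2-only regions had a median width of 220 bp and a median summit of 25.2 times the background mean, and the G128-only regions 190 bp and 24.7 times. Shared regions had a median width of 627 bp and a median summit of 60.9 times the background. Narrow and weak regions were not particular to a single group. The patterns with 2 libraries that followed no group had median widths of 177 to 193 bp and median summits of 23.7 to 23.8 times the background. Of the G2-only regions, 30 of 3820 (0.785%) ranked above the median signal of both lists that had them, against 0 of 170 G128-only regions and 15405 of the shared regions (55.5%, for all 4 lists). A region without a peak was below the caller's threshold in that library, which does not show that it was closed.

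The strongest G2-only region lay on chromosome 2 at 118354955 to 118355896, 942 bp long. Its summit was 72.8 times the background in G2 replicate 1 and 64.3 times in G2 replicate 2, where the shared regions had medians of 67.3 and 68.7 times. The next were 11:95505548–95506104, with summits of 53.7 and 52.6 times the background, and 7:71466458–71466906, with 67.3 and 63.6 times. The region at 3:20031034–20031711 reached 49.1 and 47.5 times, and that at 4:140180567–140181138 reached 55.5 and 66.5 times. Chromosome 4 also held 2 G2-only regions close to each other among the 10 strongest, at 119639086 to 119639705 and at 119862330 to 119862938. The 10 strongest G2-only regions lay on 7 chromosomes, with mean summits of 39.3 to 68.5 times the background and widths of 449 to 942 bp. Their worst ranks by signal were 12824 to 17806 in lists of 42358 and 41585 peaks.

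The strongest G128-only region lay on chromosome 12 at 81133526 to 81133840, with summits of 37.0 times the background in G128 replicate 1 and 37.6 times in G128 replicate 2. The regions at 1:151890213–151890563 and 10:57687134–57687537 followed, with summits of 29.4 and 31.2 times and of 32.2 and 33.3 times the background. On chromosome 3 lay 3 of the 10 strongest G128-only regions, at 51525648 to 51525924, at 138183932 to 138184241 and at 8245790 to 8246052. The 10 strongest had mean summits of 26.0 to 37.3 times the background and widths of 249 to 404 bp. Their worst ranks by signal were 20733 to 26819 in lists of 32540 and 37695 peaks. What lies at these positions was not annotated, since no annotation of mm9 was used here.

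In the regions with peaks in all 4 libraries, summits stood higher over the background on G2. The median summit of the 27768 shared regions was 67.3 times the background in G2 replicate 1 and 68.7 times in G2 replicate 2. It was 50.3 times in G128 replicate 1 and 58.1 times in G128 replicate 2. The group means were 68.0 ± 0.965 on G2 and 54.2 ± 5.54 on G128 (SD, n = 2 each), a ratio of 1.25, or a difference of 0.33 on the log2 scale between 6.09 ± 0.02 and 5.76 ± 0.15. This measure was chosen after the values of the lists had been seen. The two-sided exact permutation test gave p = 0.333, the smallest possible with these libraries. With the summit threshold set at 0.5 of each library's own median in shared regions, 671 regions were G2-only and 759 G128-only among the peaks that passed it. Only 130 of the 3820 and 18 of the 170 regions reached it in both lists. Most regions counted here therefore also had a listed peak of the other group, which was below the threshold of its own library. That threshold was 25.1 and 29.0 times the background in G128 replicates 1 and 2. It was 33.7 and 34.3 times in G2 replicates 1 and 2, so a G2 peak dropped by it need not have been the weaker one. With an equal threshold of 30 times the background in all libraries, also added after the values were seen, 2332 were G2-only and 112 G128-only. This threshold was reached in both lists by 304 of the 3820 and 4 of the 170 regions.

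**Figure D3:**
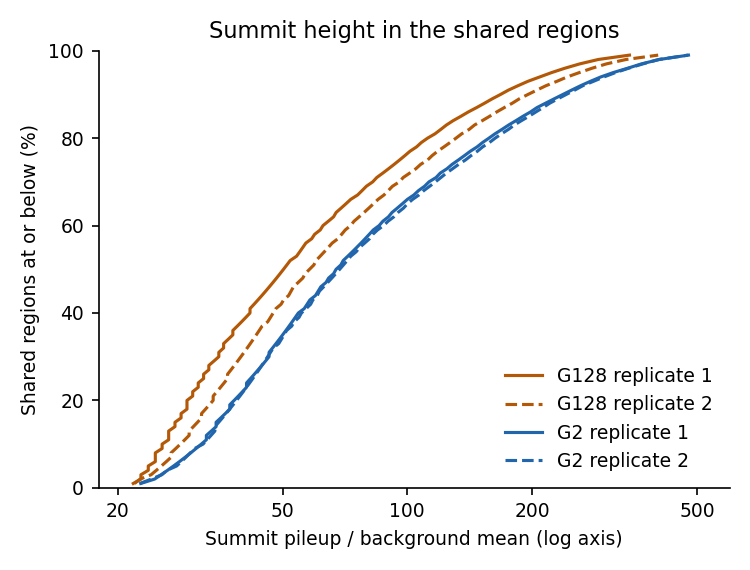
Cumulative share of the shared regions (%) with a summit at or below a given multiple of the background mean (log axis), with one line per library, G128 in orange, G2 in blue, and replicate 2 dashed. The lines of the 2 G2 libraries nearly coincide, with medians of 67.3 and 68.7, and lie to the right of the lines of G128 replicate 1 and G128 replicate 2, with medians of 50.3 and 58.1.

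Across chromosomes, the G2-only regions were most frequent on chromosome 14, with 164 regions or 20.3 per 100 shared regions, and on chromosome 18, with 115 or 17.0 per 100. They were least frequent on X, with 46 regions or 10.0 per 100, and on chromosome 11, with 262 or 10.7 per 100, apart from Y, which had none beside 7 shared regions. A chi-square test of G2-only against shared regions over 21 chromosomes gave 65.4 and a permutation p of 1e-05, the smallest that 100000 permutations can give (2e-05 after Benjamini-Hochberg adjustment over the 2 classes). With the same number of peaks from each list the permutation p was 0.574. The test compares these lists and not the conditions, since regions are not replicates.

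The G128-only regions differed from the shared regions over chromosomes with a chi-square of 87.7 and a permutation p of 0.00072, also 0.00072 after adjustment. This rested on chromosome Y, where 2 of the 170 G128-only regions and 7 shared regions lay, and the permutation p was 0.496 without Y. Peaks on Y numbered 17 and 13 in the G128 libraries and 9 and 11 in the G2 libraries.

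The widest peaks lay at 2 positions in every library. One was at 9:2999951–3038445 as called in G128 replicate 1, 38495 bp long, at the start of the assembled sequence of chromosome 9. Its summit was 1323 and 875 times the background in G128 replicates 1 and 2, and 791 and 610 times within the widest peak of G2 replicates 1 and 2. The other was at X:166426817–166447096, with summits of 979 and 1025 times the background in the G128 libraries and 1409 and 1478 times in the G2 libraries. Only G128 replicate 1 had further peaks wider than 8000 bp, both on chromosome 11, at 3026964 to 3038088 and at 3039813 to 3048299. These regions were singled out after their widths were seen.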

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

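The thresholds on the summit and all settings of the test of single shared regions were chosen after the data were seen, and the other alternatives were planned. The ratios of peaks and of bases covered between the groups, and the Jaccard difference, moved by less than the spread between replicates under the 3 or 4 alternatives tried for each. The ratio of peaks cannot be given with equal numbers of peaks. Promoter distance, gene list and motif alternatives were not run, since no mm9 genome or annotation was used here.

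For regions of a single group, 50% reciprocal overlap gave 1137 G128-only regions, and 500 bp windows around summits gave 356. Peaks in the upper part of each list by p, above its median, gave 55 G128-only and 1796 G2-only regions. A p 10 times below the weakest of the list gave 88 and 2389, and peaks of at least 200 bp gave 105 G128-only regions. Fewer peaks enter under these last 3 settings. The same number of peaks from each list gave 542 and 1385, and the strongest 10000 gave 266 and 262. An equal summit threshold of 30 times the background gave 112 and 2332, and of 40 times 54 and 1980, with fewer peaks. A summit threshold of 0.4, 0.5, 0.7 and 1 times the library's median in shared regions gave 789, 759, 459 and 343 G128-only and 966, 671, 478 and 314 G2-only regions. Leaving out each library in turn gave 363 to 1224 G128-only and 4433 to 8221 G2-only regions, where fewer libraries have to be met. The remaining alternatives stayed within 1.5 times of the counts of 170 and 3820. The ratio of G2-only to G128-only regions was 0.985 with the strongest 10000 peaks, and 1.22, 0.884, 1.04 and 0.915 at the 4 thresholds scaled to the library. Settings that drop peaks can count a region for a single group where the other group had a listed peak that was dropped. All regions counted with the strongest 10000 peaks were of this kind. At the scaled threshold of 0.5 most were, since only 130 of the 3820 and 18 of the 170 regions reached it in both lists.

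The chromosome test of G2-only regions gave a permutation p of 0.574 with the same number of peaks from each list, and the cause was not tested. Without each library in turn its p was 1e-05 to 8e-05, and for G128-only regions 1e-05 to 0.0208.

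In the test of single shared regions, with 167 higher and 240 lower on G2, omitting the median scaling gave 7384 and 61. Quantile normalization gave 43 and 77, cyclic loess 85 and 159, and a mean summit of at least 40 times the background, with fewer regions tested, 97 and 116. Leaving out each library gave 16 to 438 higher and 47 to 434 lower. Omitting the median scaling leaves in the difference of 0.33 (log2) between the median summits of the groups. Apart from this and the fewer regions and libraries, the cause was not tested.

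With the replicate number as a replicate block, this test gave 230 higher and 382 lower regions. The deviations of same-numbered libraries from their group means correlated by 0.00279 across regions, which gives no sign that the numbers pair the libraries, although same-numbered libraries were also alike in depth. For regions of a single group, the paired count is 170 and 3820 by construction. The weakest listed summits rest on 20 to 26 overlapping intervals, which limits the precision of their height, and regions below the caller's threshold have no value.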

Other observations

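The tests in this part were chosen after the results were seen. Beyond the higher median summits of the G2 libraries, some single shared regions were called different from the rest. The number called depended on the scaling and on single libraries. With each library's median removed, which takes out a shift of 0.33 (log2), limma called 167 of the 27768 shared regions higher and 240 lower on G2 at an adjusted p of 0.05. Without the median scaling it called 7384 higher and 61 lower. Of the 240 lower regions 61 were still called there. Of the 167 and 240 regions, 2 changed sign under quantile normalization, which still called 41 and 77 of them, and 0 under cyclic loess, which still called 78 and 146. The shift differed with summit height, with medians of 0.12 and 0.41 (log2) in the lowest and the ninth of 10 equal classes. Removing 1 median per library therefore took more than their own shift from the weakest regions, which favours lower calls there. Where the mean summit was at least 40 times the background, 97 higher and 116 lower regions were called. The region at 4:62889872–62890567 rose from 50.3 and 46.8 times the background in the G128 libraries to 130.1 and 145 times in the G2 libraries, which with the medians removed is a log2 change of 1.17 ± 0.15 (SE, limma adjusted p 1.96e-05). The regions at 15:87545485–87546154, 6:85805964–85806769, 10:77767697–77768254 and 2:174169462–174169980 rose by 1.01, 0.90, 1.18 and 1.00 with the medians removed, and by 1.34, 1.23, 1.51 and 1.33 without this. The region at 1:194571748–194572699 went from 45.5 and 58.8 times the background on G128 to 25.5 and 26.3 times on G2 (log2 change −0.999, or −1.33 ± 0.20 with the medians removed, limma adjusted p 0.000152). The regions at 3:154291172–154291656, 3:35579366–35579910, 9:2999951–3038445 and 17:13743499–13746092 had changes of −1.29, −0.98, −0.88 and −0.76 with the medians removed, and of −0.96, −0.65, −0.55 and −0.43 without this. The one on chromosome 9 is the 38495 bp region at the start of the assembled sequence described above. No regions were filtered out here as repeats or artifacts. For these 10 regions, the 5 with the smallest p in each direction, both G2 libraries lay on the same side of both G128 libraries, which a choice by p from the same values makes likely.

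The calls depended on single libraries. Without G2 replicate 1 there were 22 higher and 96 lower regions, and without G2 replicate 2 there were 16 and 47. Without G128 replicate 1 there were 424 and 205, and without G128 replicate 2 there were 438 and 434. The lone library of a group is then assumed to vary like the others. The 2 other ways to split the libraries into pairs gave at most 1 call, with 452 and 633 regions at an unadjusted p under 0.05 against 4164 for the real split, but 3 splits are too few for a share under 0.05. Both sides of these other splits mixed the groups, so any difference between the groups entered the residual spread and lowered their counts. They therefore do not show how many calls would arise without a group difference.

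The first pattern weighed was the excess of G2-only over G128-only regions, 3820 against 170. Deeper sequencing of the G2 libraries is argued against as the whole account, because G2 replicate 2 had 41585 peaks against 37695 in G128 replicate 2 at 0.970 times its background mean, although G2 replicate 1 had 42358 against 32540 in G128 replicate 1 at 1.04 times its background mean. Higher summits across the shared regions stay open as an account: with a threshold of 0.5 of each library's median summit the ratio of G2-only to G128-only regions was 0.884, and with equal thresholds of 25, 30 and 40 times the background it was 15.2, 20.8 and 36.7. The scaled threshold takes out the difference in median summit between the libraries, which by itself moves the ratio towards 1. Only 130 of the 3820 G2-only regions (3.40%) reached it in both lists. For most of the regions in question, higher summits across the shared regions therefore cannot be told apart from changes of single regions. Whether the higher summits reflect the culture condition or the reaction and quality of each library also stays open, since the design ties library to condition with 2 libraries each.

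The second pattern was that regions lower on G2 gathered in unusual places, which were singled out after the calls were seen. Of the 240 lower regions, 28 (11.7%) lay in 200 kb windows of at least 40 regions, had summits of at least 1000 times the background or lay on Y, against 227 (0.817%) of all shared regions and 0 of the 167 higher ones, and no p-value is given since regions of one window are not independent. Without median scaling the 205 shared regions of the dense windows had a median change of 0.0185 (log2), with −0.15 at 8:19800001–20000000, −0.08 at 8:126000001–126200000, −0.03 at 11:3000001–3200000, 0.05 at 6:114400001–114600000 and 0.33 at 19:5800001–6000000, and the highest summits and Y had −0.10 and −0.35. The dense windows, in the order above, held 3, 7, 4, 1 and 0 of the lower regions. The chromosome 19 window, which held none, lay near the median of 0.34 for all shared regions. Whether reads in the dense windows follow the amount of DNA more than its accessibility cannot be told apart from other accounts. Copy number was not measured, and the windows with lower regions had medians on both sides of 0, from −0.15 to 0.05. For the other 212 lower regions the same question stays open: their median change was −0.43 ± 0.17 (SD), below 0 in all 212 and in both pairs for 194, but they were called by these values, and 212 regions chosen as lowest in the replicate 2 pair had −0.00423 ± 0.024 (SE) in the replicate 1 pair, against 0.43 for all shared regions there, while the reverse choice gave −0.13 ± 0.03 against 0.24.

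The third pattern was that neighbouring shared regions changed together. The change of a region in the replicate 1 pair correlated with the change of its neighbour in the replicate 2 pair by 0.164 at under 2000 bp, 0.128 at 2000 to 10000 bp, 0.0752 at 10000 to 100000 bp and 0.0171 at 100000 to 300000 bp. A lack of order along the chromosome is argued against by a permutation p of 0.000999 at under 2000 bp, the smallest that 1000 shuffles can give. The dense windows, highest summits and Y alone are argued against as the source, because without them the correlation was 0.0724 at 2000 to 10000 bp, with 0.0221 the highest of the shuffles, although this is less than with them, as is the 0.0312 left at 10000 to 100000 bp. Changes spread over several regulatory elements of a neighbourhood, and copy number differences between the cultures, both stay open as untested. The shuffles kept the chromosome of a region but not its summit height, with which the change also varied. Whether neighbours changed together only because their summits were alike in height was therefore not tested either.

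The change on G2 without median scaling was smaller in the weakest shared regions. Its median was 0.12 (log2) in the lowest of 10 equal classes by summit, 0.33 in the fifth class and 0.41 in the ninth. The weakest regions are those closest to the caller's threshold, which every library had to pass. On chromosome Y, the 7 shared regions had medians of 40.8 and 33.3 times the background in the G128 libraries and 30.02 and 24.8 times in the G2 libraries, while the 459 shared regions of X had 53.1, 63.8, 76.4 and 78.9 times.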
